A study of Mus musculus with 8 samples.

How the data were processed

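Splenic CD8+ T cells of OT-I mice were profiled on 8 single-colour Agilent mouse arrays, 4 on each of 2 slides. Per the file headers the scanner files hold processed signal as linear intensity, made by the authors with Agilent Feature Extraction 10.7.3.1 by background subtraction with spatial and multiplicative detrending within each array, and not normalized between arrays. Per the submitters' processing notes the version was 9.5.3.1. Coordinates are those of build mm9 in the headers. The deposited series values are also intensity, and each column was found to equal 1 array's processed signal times 1 factor (1.209 to 1.857), with the 75th percentile at about 1500 and values under 15 set to 15. Its column medians were 89.57, 102.4, 92.62, 95.78, 92.25, 100.6, 80.68 and 73.76. Its scale, centring and direction followed from this match.

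The value table's columns for TCR 1 h and for IFNβ 1 h with TCR 1 h matched each other's scanner file, with an SD of the log2 ratio of at most 2.1e-10, and 6 columns matched their own file. The value table's assignment was used, a choice made after the antiviral genes had been seen. Each array had 45018 spots, 1639 of them controls, for 41174 probes. Between 100 and 246 spots per array marked as outliers were left out, and repeated spots were averaged on the log2 scale. Probes were kept when well above background on at least 2 arrays (28708), log2 signal was scaled to the 75th percentile, and the brightest probe of each gene gave 19919 genes. By accession 26690 probes were matched to a gene, 3169 of them with a symbol other than the file's, and 14484 kept the file's name. Scaled signal in the text is on a linear scale with the 75th percentile at 1500.

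By robust SD the untreated arrays differed by about the spot noise of 1420 spots of 145 repeated probes (per spot 0.0588 between the arrays, 0.0803 and 0.0745 within them), while the plain SD of probe means was 0.0603 against 0.0483 expected from spot noise. Their mean was counted as 1 sample, a departure from the planned design made after the data were examined, and the planned version is given as an alternative. Linear models were fitted with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8). The additive model had IFNβ, TCR 1 h and TCR 6 h as terms over 7 samples, with 3 residual degrees of freedom. Further models had the IFNβ by TCR interactions (1 residual degree of freedom) and late against early IFNβ (2 residual degrees of freedom). In the interaction model the arrays for IFNβ 2 h and 7 h shared 1 mean, as IFNβ without TCR. Its residual degree of freedom came from the difference between these 2 arrays. P values were moderated and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Leave-outs that left 1 array in an arm assumed that this array varied like the others. In the additive model an array left alone at its TCR time added nothing to the IFNβ term. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

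The comparisons, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. The rule named up to 12 genes in each direction with the largest changes among those that passed and had the same sign in every pair of arrays (8 where a comparison has no such pairs, or the 5 largest well above background on all 8 arrays where none passed), the 4 largest of each list, and a fixed set of genes always given, not all of which are reported here: Irf7, Isg15, Ifit1, Egr1, Nr4a1, Cd69, Il2ra, Ifng, Il2, Gzmb, Myc, Ifnar1, Ifnar2, Ccr7, S1pr1 and Cxcr3. Names that are only clone or accession identifiers were passed over. Genes shown by their signal on single arrays come from the same set.

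The 24 lists were antiviral genes, interferon-inducible GTPases, JAK-STAT and IRF, class I presentation, immediate early response, NF-kB, activation and costimulatory receptors, cytokines and chemokines, cytotoxic effectors, naive state, chemokine receptors and migration, effector and memory transcription factors, apoptosis and survival, MYC and ribosome biogenesis, glycolysis and nutrient uptake, cell cycle, TCR signalling, stress and unfolded protein response, and markers of B cells, class II presenting cells, myeloid cells, NK cells, CD4 T cells and erythroid cells. They were tested with camera (preset correlation 0.01, and again with an estimated correlation), after leaving out 232 genes with missing values. Single-array medians were set against 10000 random lists matched in 20 bins of mean signal.

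The models were tested on simulated data with 19687 genes. Changes of a log2 of 2 were recovered for 63 of 67 genes for IFNβ, 48 of 67 for TCR 1 h and 51 of 67 for TCR 6 h, with 13, 10 and 13 calls among unchanged genes. Changes of a log2 of 1 were recovered for 6, 0 and 2 of 67. The changed genes were drawn at random and given no interaction or duration effect. These rates therefore do not carry over to genes with such effects: in the data Mx1, at 7.07 ± 0.92 for IFNβ, missed the threshold. Alternatives covered background correction, scaling, filter, probe summary, slide as a block, variance trend, model and each array left out. Because the untreated arrays were averaged, the slide term of the additive model was the difference between the IFNβ 7 h and IFNβ 2 h arrays. Results with slide as a block therefore do not separate slide from the length of IFNβ treatment. A model with 1 mean per condition was left out because it has no residual degrees of freedom.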

Results

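Messenger RNA was measured on 8 single-colour oligonucleotide arrays carrying cRNA from splenic CD8+ T cells of OT-I mice, whose transgenic T cell receptor (TCR) recognises the ovalbumin peptide SIINFEKL on the class I molecule H-2Kb. Cells were left untreated (2 arrays), given interferon beta (IFNβ) alone for 2 h or 7 h, stimulated through the TCR with SIINFEKL streptamers for 1 h or 6 h, or given IFNβ for 1 h and then stimulated through the TCR for 1 h or 6 h, with 1 array per treated condition. The series asks how type I interferon modulates T cell responses. The 75th percentile of the processed signal lay between 807 and 1240 intensity units per array, and between 26065 and 29533 of the 43379 non-control spots on an array were well above background. The number of arrays limits the precision. No treated condition had a replicate array, so every test compared groups of arrays that shared a treatment.

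The 2 untreated arrays were close to each other at repeated probes. Over 145 of these the robust SD of the log2 difference between the arrays was 0.0354, against 0.0346 expected from spot noise alone, and the plain SD was 0.0603, against 0.0483 expected. Their mean was counted as 1 sample and each test had 7 samples. At least 2-fold differences between the 2 untreated arrays were seen for 594 of 19808 genes, and the SD of that log2 difference over genes was 0.36. The arrays for TCR 1 h and for IFNβ 1 h with TCR 1 h carried opposite identities in the 2 deposited sources: the value table's column for each was an exact multiple of the other's scanner file, while the other 6 columns matched their own file. The value table's assignment was used, under which the median of 57 antiviral genes lay 4.44 log2 above untreated after IFNβ 1 h with TCR 1 h and at -0.14 after TCR 1 h. Because these genes favour that assignment, the interferon difference within this pair of arrays is not independent evidence of an IFNβ effect.

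A small set of genes passed the threshold for IFNβ, antiviral genes among them. Ifit3 (chromosome 19, 34663105 to 34663164 in mm9) rose 164-fold, a log2 change of 7.36 ± 0.42 (SE, 4 arrays with IFNβ against 3 samples without, adjusted p = 0.016). Rtp4 rose 20-fold (4.32 ± 0.25, adjusted p = 0.016), and Ifit3b rose 223-fold (7.80 ± 0.62, adjusted p = 0.034, well above background on 3 of 4 arrays without IFNβ). Xaf1 rose 21-fold, Oas1b 13.4-fold, Trim34a 6.72-fold and Col23a1 6.67-fold. Each of these 7 genes was higher with IFNβ in 4 of 4 pairs of arrays, which was a condition for being named. The naming of the pair at TCR 1 h was chosen by antiviral genes. For such genes its sign is therefore no evidence, and the adjusted p values rest on the same choice. All 7 calls were lost without that pair, on slide 2 alone, and with quantile normalization, with or without normexp background correction. Among 19919 genes tested with limma, 10 passed the adjusted threshold, all higher, and 3 of them had no usable gene name. An unadjusted p under 0.05 was reached by 1706 genes.

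Several well-known interferon targets had high estimates and missed the threshold. The log2 difference was 7.07 ± 0.92 for Mx1 (adjusted p = 0.093), 6.99 ± 0.81 for Mx2, 6.99 ± 0.84 for Usp18, 6.55 ± 0.75 for Ifit1 (adjusted p = 0.083), 5.51 ± 0.52 for Isg15 (adjusted p = 0.051) and 4.17 ± 0.42 for Irf7. The receptor subunit genes Ifnar1 and Ifnar2 stood at 0.12 and 0.78. Values for the chemokine receptor genes were -0.28 for Ccr7 and -1.08 for Cxcr3, and none of these 4 genes passed. With the 2 untreated arrays taken as separate samples, as first planned, 84 genes passed, 77 higher and 7 lower. The count of 10 was 0 without any 1 of the arrays for IFNβ 2 h, IFNβ 7 h, TCR 1 h or IFNβ 1 h with TCR 1 h, and 275 without the array for TCR 6 h or for IFNβ 1 h with TCR 6 h. It was 0 with the scanner files' assignment of the disputed pair and 0 without that pair. For the IFNβ term, leaving out either array of a TCR pair is the same fit as leaving out the pair. Those leave-outs are therefore not separate checks.

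The antiviral genes had the highest median of the 24 lists in the IFNβ response. Their median log2 difference was 3.75 over 57 measured genes, of which 4 passed over all genes (16 with slide as a block) and 56 passed adjusted over the list alone. The 15 interferon-inducible GTPases had a median of 3.05, with 0 passing over all genes in limma and 15 adjusted over the list alone. Iigp1 stood at 5.21 ± 1.32, Gbp6 at 4.38 ± 0.80, Gbp5 at 3.51 ± 0.98 and Gbp7 at 3.44 ± 0.78. Medians were 0.65 for 22 class I presentation genes, 8 of which passed adjusted over the list alone, and 0.51 for 24 JAK-STAT and IRF genes, with 3 passing adjusted over the list alone. Markers of other cells had medians of the same size, 0.66 for NK cells and 0.50 for B cells. Stat2 had an estimate of 3.34 and Irf9 of 1.63, Tap1 of 1.72, Psmb10 of 1.78 and Psmb9 of 1.53.

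Metabolic and growth lists lay on the other side of 0 with IFNβ. The median was -0.44 for 48 genes of MYC and ribosome biogenesis, -0.34 for 31 of glycolysis and nutrient uptake and -0.41 for 27 of stress and the unfolded protein response. Slc16a3 stood at -1.83 ± 0.27, Tpi1 at -1.09 and Hspa1a at -1.67. For activation receptors the median was -0.14 and the mean 0.23, and for cytotoxic genes -0.06 and 0.28. The cytokine list had 6 members higher and 1 lower adjusted over the list alone, with Cxcl10 at 5.08, Tnfsf10 at 3.54, Csf1 at 3.30 and Cxcl11 at 2.66 (well above background on 1 of 4 arrays without IFNβ). With the preset correlation in camera, 13 of 24 lists passed in this comparison, 8 higher and 5 lower, among them the antiviral genes (adjusted p = 5.2e-70, and adjusted p = 0.43 with an estimated correlation), the GTPases (7.5e-19, and 0.48) and the MYC list (2e-11, and 0.54). The same test gave 14 lists for TCR 1 h and 14 for TCR 6 h, and no call of camera in any comparison held with an estimated correlation. Under the scanner files' assignment the antiviral median in this comparison was 0.98.

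On single arrays the antiviral genes were high after both durations of IFNβ. Their median lay 3.19 log2 above untreated at 2 h and 4.97 above at 7 h, with 57 of 57 genes higher on each array. The scaled signal of Mx1 was 96 and 93.3 in untreated cells, 23200 after IFNβ for 2 h and 73400 after 7 h. The GTPases had medians of 3.39 at 2 h and 4.08 at 7 h. At least 2-fold differences from the untreated mean were seen for 3051 genes at 2 h, 1998 higher and 1053 lower, and for 3551 at 7 h, 2130 higher and 1421 lower. After IFNβ 1 h with TCR 1 h the median lay 4.66 log2 above TCR 1 h, and after IFNβ 1 h with TCR 6 h it lay 2.32 above TCR 6 h. The median at 6 h was above all 10000 random lists of the same size and expression. Single arrays have no replicate error.

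**Figure D1:**
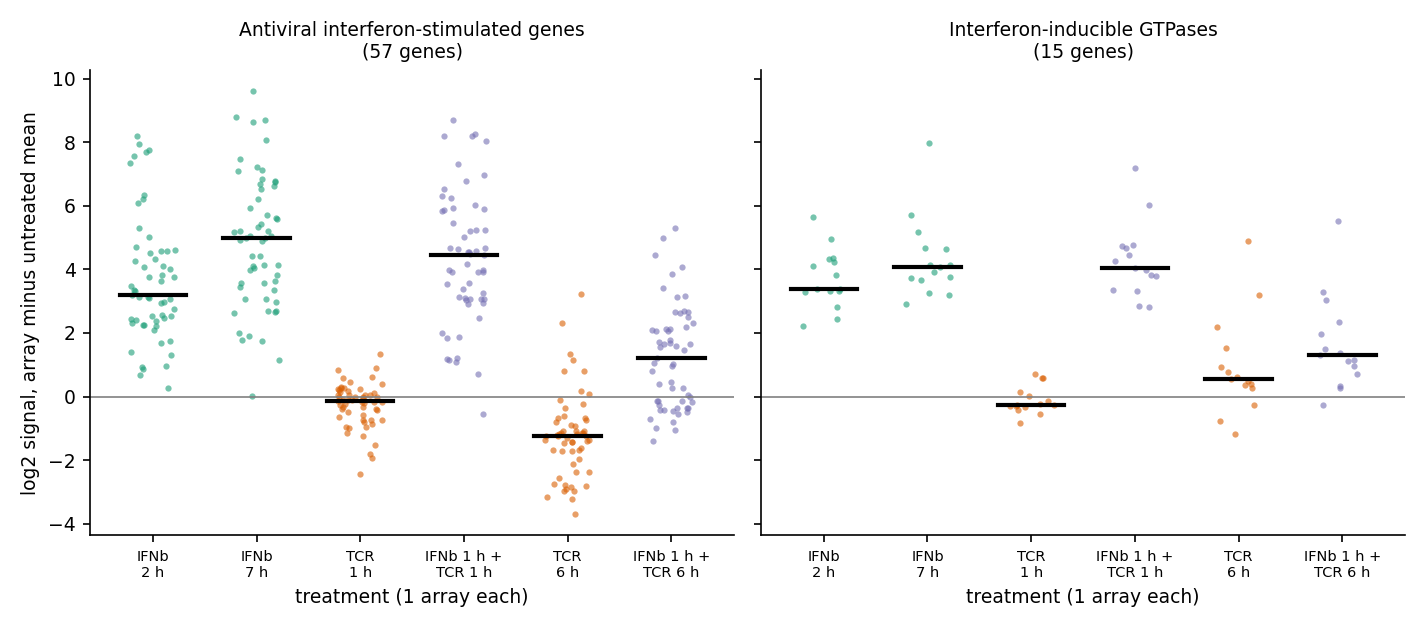
Log2 signal of each measured antiviral gene (left, 57) and interferon-inducible GTPase (right, 15) on each treated array minus the untreated mean; points are genes and black bars are medians. The antiviral medians lay between 3.19 and 4.97 on the arrays for IFNβ 2 h, IFNβ 7 h and IFNβ 1 h with TCR 1 h, and at 1.21 after IFNβ 1 h with TCR 6 h.

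TCR stimulation for 1 h raised single cytokine and immediate early genes by more than 100-fold. Ccl3 rose 473-fold (8.89 ± 0.70, SE, 2 arrays against 3 samples, higher in 2 of 2 pairs of arrays, adjusted p = 0.0063) and Ifng rose 373-fold (8.54 ± 0.30, adjusted p = 0.0017). Tnf rose 214-fold, Tnfsf14 195-fold, Nr4a2 213-fold, Egr3 141-fold and Atf3 113-fold. Nr4a3 rose 142-fold, with 1 of 4 arrays without TCR well above background. Between plain group means, not adjusted for IFNβ, Egr4 was at least 424.5-fold and F3 at least 457.1-fold higher. Such bounds are given where a gene was not well above background on any array of 1 group. That group's level was then taken as the lowest signal well above background where that was higher. The fitted changes, adjusted for IFNβ, were 416-fold for Egr4 and 412-fold for F3. The bounds here and for TCR 6 h against no TCR are therefore not bounds on the fitted change. Egr1 rose 67.9-fold, Nr4a1 45.5-fold, Tbx21 42.9-fold, Irf4 34.4-fold and Myc 27.4-fold, Il2 97.5-fold (6.61 ± 0.89, adjusted p = 0.022) and Il2ra 4.79-fold.

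Fewer genes fell at 1 h. Lrrc75b fell by 3.85 on the log2 scale (SE 0.40, adjusted p = 0.013), Cnr2 by 3.04 and Txnip by 2.80. Values for genes that missed the threshold were 3.21 for Cd69 (adjusted p = 0.053), 1.78 for Gzmb, 1.82 for Cxcr3 and -1.93 for Ccr7. With limma, 826 of 19916 genes passed, 490 higher and 336 lower, and the share of higher calls was 59.3%. After normexp background correction and quantile normalization 1886 genes passed, 788 higher and 1098 lower, a share of 41.8%. With the untreated arrays as separate samples the count was 2534, 1244 higher and 1290 lower. The count was 30 without the array for TCR 1 h, 85 without IFNβ 1 h with TCR 1 h, 86 without IFNβ 2 h and 115 without IFNβ 7 h, and of 29 named calls 19, 16, 9 and 10 were lost in those fits. Slide as a block left 43 genes, 37 higher and 6 lower, slide 1 alone gave 429, and the scanner files' assignment gave 356.

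Immediate early genes led the lists at 1 h. Of 36 measured, 27 rose over all genes, and 33 were higher and 1 lower adjusted over the list alone, with a median of 3.47 (camera adjusted p = 9e-31, and adjusted p = 0.14 with an estimated correlation). In the list of MYC and ribosome biogenesis, 15 of 48 genes rose, 37 adjusted over the list alone, with Gnl3 at 2.41, Rrs1 at 2.40 and Tsr1 at 2.33. Activation and costimulatory receptors had 10 of 30 genes risen, led by Cd160 at 5.32, Slamf7 at 4.79 and Slamf1 at 4.61. In the NF-kB list 6 of 19 genes rose, among them Nfkbid at 5.49, Rel at 3.87 and Nfkbiz at 2.53. Cytokines and chemokines had 8 members risen and 1 fallen of 31. The stress list had 5 of 27 risen, with Chac1 at 2.86 and Atf4 at 2.06, and glycolysis and nutrient uptake had 6 of 31, with Slc7a1 at 2.18 and Hk2 at 1.65. Naive-state genes had 1 risen, Tob2 at 3.02, and 4 fallen of 31. With the untreated arrays as separate samples the naive-state median was -0.68. Medians of B cell, class II and NK cell markers were then -0.62, -0.67 and -0.81, with 0 of these markers called. On the TCR 1 h array alone, against untreated, the naive-state median was -0.73 and those of the markers -0.11, -0.04 and 0.12. With slide as a block the calls over all genes were 9 for immediate early genes, 3 for cytokines and chemokines, 1 each for the NF-kB and stress lists, and 0 for the MYC list (17 adjusted over the list alone), activation receptors, glycolysis and the naive state.

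Genes of further lists also passed at 1 h. Effector and memory transcription factors had 4 of 30 risen, including Irf8 at 3.20. Apoptosis and survival genes had 4 risen and 2 fallen of 36, with Gadd45b at 3.81 and Bcl2a1b at 3.61. Chemokine receptors and migration genes had 3 risen and 2 fallen of 34, with Rgs16 at 3.82 and Itga4 at -2.44. TCR signalling components had 4 of 38 risen, with Lcp2 at 2.47 and Ptpn6 at 1.95. Cell cycle genes had 1 risen, Cdkn1a at 5.21, and 3 fallen of 37. The cytotoxic list had 1 of 24 risen, Crtam at 4.17. With slide as a block 3 of the transcription factors kept a call and 0 genes of the other lists here did.

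After 6 h of TCR stimulation Il2 reached a 1330-fold rise (10.38 ± 0.89, SE, 2 arrays against 3 samples, adjusted p = 0.00055; chromosome 3, 37024756 to 37024815 in mm9) and Il7r fell by 7.37 on the log2 scale (SE 0.26, adjusted p = 0.00028; chromosome 15, 9435976 to 9436035). Ccl3 rose 1290-fold, Xcl1 971-fold, Csf2 538-fold (9.07 ± 1.31), Rgs16 362-fold and Ifng 311-fold. Cth rose 674-fold, and Bcat1 had a log2 change of 7.83. Csf2 and Cth were well above background on 2 of 4 arrays without TCR, and Il2 on 3 of 4. Il2ra rose 73.5-fold, Gzmb 23.3-fold, Myc 26.6-fold and Cd69 6.27-fold. Cd7 fell by 6.82, S1pr1 by 6.59 and Cnr2 by 5.88 on the log2 scale. The log2 changes of Rflnb and Slc28a2 were -7.81 and -6.93. Lrrc75b was at least 163-fold lower and Slc6a19 at least 220.9-fold lower.

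The response at 6 h covered much of the measured transcriptome. With limma 8921 of 19917 genes passed, 4411 higher and 4510 lower, and 7814 of them differed by over 2-fold. Scaling to the array median in place of the 75th percentile moved the median of all genes from 0.045 to 0.374 log2 and the share of higher calls from 49.4% to 62.7%, so directions are relative to the 75th percentile. The count was 4695 without the array for IFNβ 1 h with TCR 6 h, 5682 with slide as a block and 6432 on slide 2 alone. The untreated arrays as separate samples gave 10417. Cd69 lost its call without the TCR 6 h array.

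Most genes of the growth, metabolic and stress lists rose at 6 h. All 48 genes of MYC and ribosome biogenesis rose, with a median of 3.35 (camera adjusted p = 1.8e-21, and adjusted p = 0.46 with an estimated correlation). Srm rose 58.3-fold, Grwd1 26.7-fold and Nolc1 25.3-fold. In glycolysis and nutrient uptake 25 of 31 genes rose and 3 fell, with Hk2 up 94.3-fold (6.56 ± 0.21, adjusted p = 0.00028), Tpi1 30.9-fold and Slc7a5 26.6-fold. The stress list had 19 of 27 risen, with Chac1 up 88.7-fold and Asns 30.2-fold. Of 31 naive-state genes 23 fell and 2 rose, with a median of -3.00. Markers of other cells fell in the same comparison, with medians of -2.21 for B cells and -1.63 for class II genes. Klf3 fell by 6.20, Dgka of the TCR signalling list by 4.37, Cdkn2d by 4.32 and Rbl2 by 4.21 on the log2 scale.

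Among effector genes, 17 of 31 cytokines rose and 2 fell, 19 of 30 activation receptors rose, and 10 of 24 cytotoxic genes rose and 5 fell. Tnfrsf9 rose 119-fold, Cd160 101-fold, Gzmc 103-fold and Serpinb9 17.6-fold, while Gzma fell by 3.86 on the log2 scale. Of 36 immediate early genes 27 were above the level without TCR and 2 below it, with Fosl1 at least 210.4-fold higher and Spry1 248-fold higher. NF-kB genes had 9 risen and 3 fallen of 19, effector and memory transcription factors 13 and 6 of 30, migration genes 7 and 16 of 34, apoptosis genes 8 and 8 of 36, cell cycle genes 6 and 11 of 37, and TCR signalling components 10 and 14 of 38. The medians of the apoptosis and TCR signalling lists, -0.17 and -0.18, were 0.16 and 0.14 with median scaling. For the cell cycle list the median was 0.03 while the mean was -0.36 and camera pointed down, and for apoptosis genes the mean was 0.25. In the JAK-STAT list 3 rose and 11 fell of 24, with Socs3 lower by a log2 change of -4.20, Ifngr1 of -3.65 and Ifngr2 of -3.58. Ifnar1 fell by 1.52 (SE 0.25, adjusted p = 0.0041).

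Antiviral genes were lower on the arrays with 6 h of TCR stimulation. The median of the list was -2.30, and 36 of 57 genes were lower over all genes, 41 adjusted over the list alone (camera adjusted p = 7e-08, and adjusted p = 0.51 with an estimated correlation). Estimates were -4.15 for Oas2, -4.26 for Slfn5, -4.01 for Oas1b and -3.02 for Irf7. Ifit1 stood at -3.23 (SE 0.89, adjusted p = 0.027), a call lost without the array for IFNβ 2 h, for IFNβ 7 h or for IFNβ 1 h with TCR 6 h. The median difference was -1.24 in the pair without IFNβ (TCR 6 h minus untreated) and -3.67 in the pair with it (IFNβ 1 h with TCR 6 h minus IFNβ 7 h). By their labels the arrays of the latter pair differed in the length of IFNβ treatment as well as in TCR stimulation. The labels do not say whether IFNβ stayed on the cells during TCR stimulation. Under the scanner files' assignment 2 of the antiviral genes passed. The class I presentation list had 3 genes risen and 4 fallen of 22, and 2 of 15 GTPases were lower. Without IFNβ the GTPases went the other way, with a median of 0.54 after TCR 6 h and 12 of 15 genes above untreated. With slide as a block 0 class I genes rose. In the TCR 6 h response the B cell markers had a median of about the same size as the antiviral list. Most class II and NK cell markers were lower there too.

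From 1 h to 6 h of stimulation, most genes of the MYC and glycolysis lists went up further. Most naive-state genes came down, as did 17 of 36 immediate early genes. Cth was 258-fold higher at 6 h than at 1 h (8.01 ± 0.40, SE, 2 arrays against 2, adjusted p = 0.0014) and Bcat1 283-fold higher. Hk2 was 30-fold higher, Il2ra 15.3-fold, Tnfrsf9 41.8-fold and Gzmb 6.78-fold. Egr1 was lower by a log2 change of -2.34, Egr3 of -4.68, Fos of -3.26 and Zfp36 of -3.49. Il7r was lower by -6.26, S1pr1 by -5.04 and Itgae by -4.86, and Fry was at least 98.23-fold lower. Of 48 genes in the MYC list 45 were higher, of 31 glycolysis genes 22 were higher and 3 lower, of 31 naive-state genes 21 were lower and 1 higher, and of 36 immediate early genes 17 were lower and 1 higher.

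Limma called 6324 of 19914 genes in this comparison, 3243 higher and 3081 lower at 6 h. Median scaling gave 6890, with the share of higher calls at 65.3% against 51.3% and the median of all genes at 0.351 against 0.072. The 2 times lay on different slides, and slide as a block left 0 calls in limma, while values taken relative to the untreated array of the same slide gave 6449. With slide as a block, the slide term equalled the difference between the IFNβ 7 h and IFNβ 2 h arrays. The 0 calls therefore do not separate slide from the length of IFNβ treatment. The count was 2780 without IFNβ 1 h with TCR 1 h, 2978 without IFNβ 1 h with TCR 6 h and 3816 without TCR 1 h, and Il2, at 3.77, lost its call without either array that had both treatments. Gzmb lost it without TCR 1 h or without TCR 6 h.

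**Figure D2:**
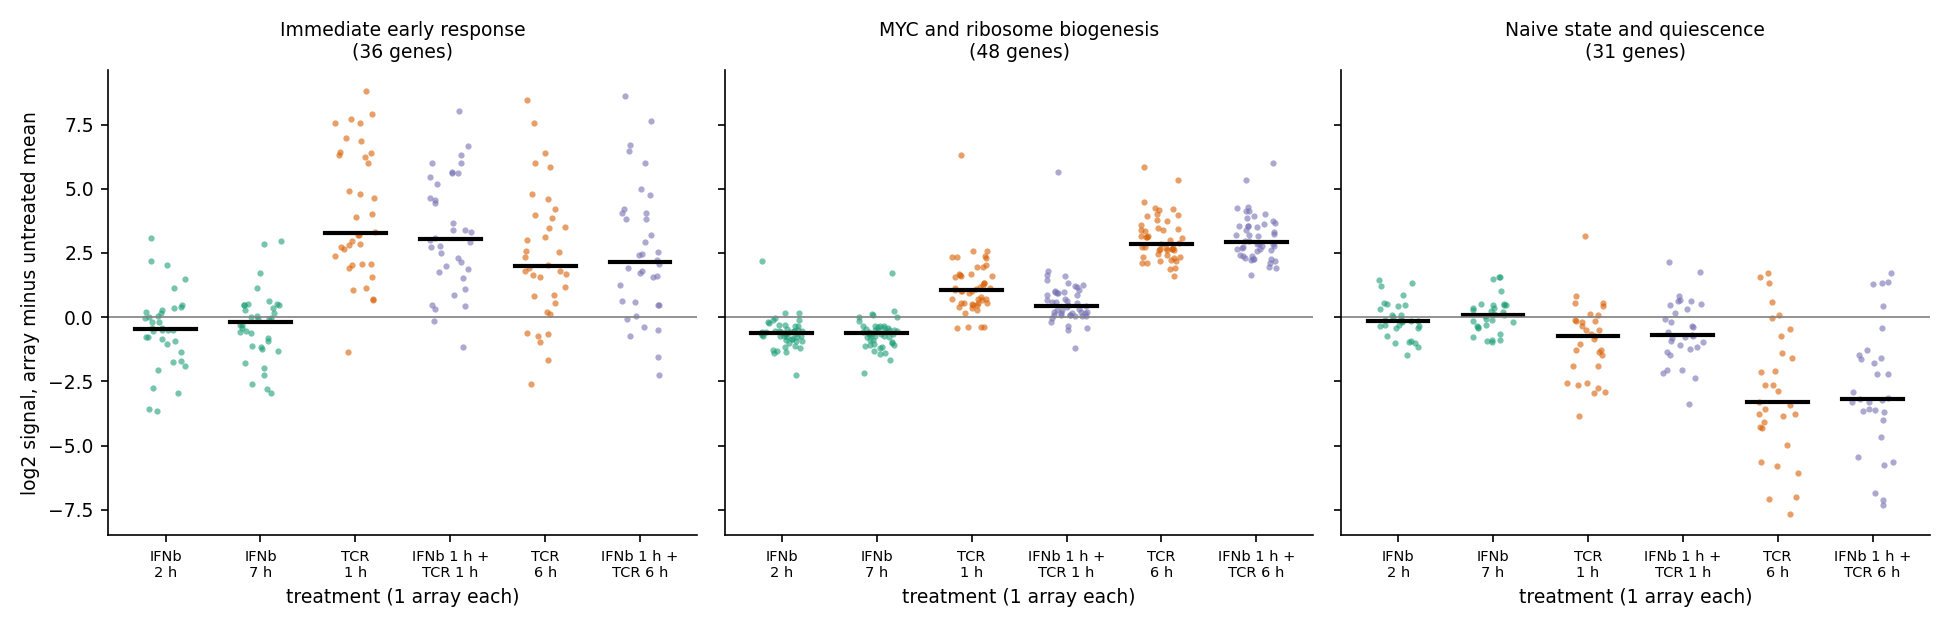
Log2 signal on each treated array minus the untreated mean for genes of the immediate early response (36), MYC and ribosome biogenesis (48) and the naive state (31); points are genes and black bars are medians. The MYC medians were 1.05 at TCR 1 h and 2.87 at TCR 6 h, and the naive-state medians -0.73 and -3.30.

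Whether IFNβ changed the early TCR response was read from the arrays stimulated for 1 h and from the interaction term. Il2 had a scaled signal of 19300 after TCR 1 h and 1130 after IFNβ 1 h with TCR 1 h, against 45.9 and 50.1 in untreated cells. Csf2 stood at 796 and 49, Il3 at 1590 and 133, Xcl1 at 96400 and 8960, and Tnf at 77300 and 27900. Ifng stood at 102000 and 133000, Cd69 at 361000 and 310000 and Egr1 at 306000 and 260000. Over 31 cytokines and chemokines the median difference, IFNβ 1 h with TCR 1 h minus TCR 1 h, was -0.97, and 14 genes were at least 2-fold lower and 7 at least 2-fold higher. The median of the same list above untreated was 1.44 after TCR 1 h and 2.88 after IFNβ 1 h with TCR 1 h, so the 2 summaries point opposite ways. Immediate early genes had a median of -0.69 and the MYC list of -0.61, both below all 10000 random lists matched on expression, which describes these 2 arrays and not the conditions. After IFNβ alone, against untreated, the MYC median was -0.61 at 2 h and -0.62 at 7 h. That of immediate early genes was -0.46 and -0.2. Lower values of these lists with IFNβ were therefore not particular to TCR-stimulated cells. The directions between the 2 arrays stimulated for 1 h turn around if the scanner files name them rightly.

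The interaction term took IFNβ without TCR as the mean of the IFNβ 2 h and 7 h arrays. Its SEs rest on the difference between those 2 arrays and not on replicates. The interaction estimate at 1 h was -3.50 ± 0.51 for Xcl1 and -1.49 ± 0.46 for Cxcr3. For Il2 it was -3.72, with the array for IFNβ 2 h not well above background. Csf2 in untreated cells, and Il3 there and after IFNβ 2 h, were not well above background, so their estimates are left out. No gene passed with limma (0 of 19819, 1515 at an unadjusted p under 0.05, adjusted p = 0.57 for Xcl1), with 1 residual degree of freedom. In simulated data of the same design, 0 of 200 genes changed by a log2 of 4 were recovered for this kind of term at 6 h. Among cytokines 8 of 31 were lower adjusted over the list alone. Markers of other cells were lower in this term too, with a median of -1.88 for NK cell markers, 6 of 12 of them lower adjusted over the list alone, and of -1.42 for B cell markers, with 0 of 16. Under the scanner files' assignment 65 genes passed, 2 higher and 63 lower. Among genes well above background on all arrays the largest estimates were -6.59 for Gadd45g, -4.82 for Daglb and -4.72 for Insl6, and 3.66 for Fosl2, 3.59 for Gpat3 and 3.58 for Gatm. The median of all genes in this term was -0.153, and -0.02 after normexp and quantile normalization.

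**Figure D3:**
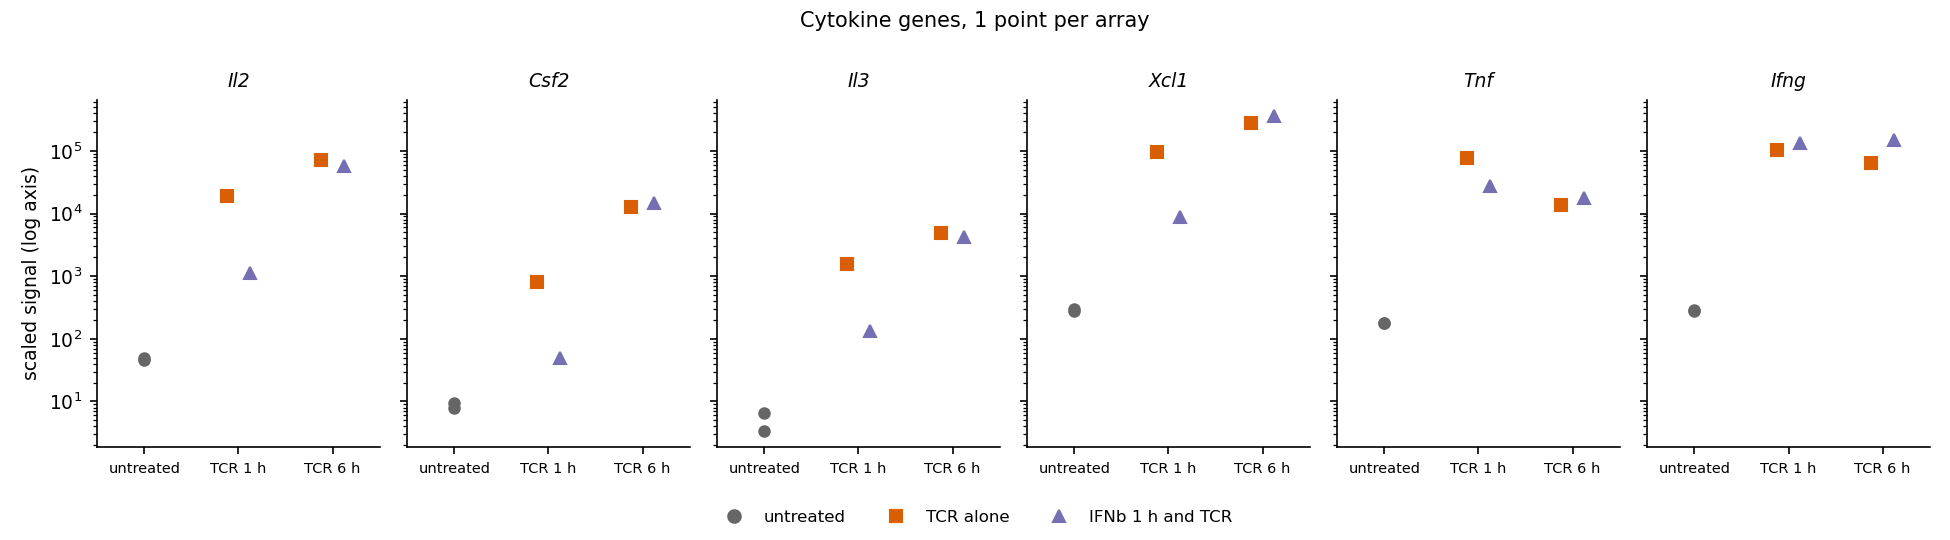
Scaled signal (log axis) of 6 cytokine genes, 1 point per array, in untreated cells and after 1 h or 6 h of TCR stimulation without (squares) and with (triangles) IFNβ for 1 h beforehand. Il2 stood at 19300 and 1130 at 1 h and at 71400 and 57200 at 6 h, under the value table's naming of the 1 h arrays.

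At 6 h the arrays with and without IFNβ were closer. At least 2-fold differences were seen for 1124 genes, 463 higher and 661 lower with IFNβ, against 3121 at 1 h and 594 between the untreated arrays. Il2 stood at 71400 after TCR 6 h and 57200 after IFNβ 1 h with TCR 6 h, Ifng at 63800 and 148000, Gzmb at 45700 and 51200, and Il2ra at 21400 and 25600. Cytokines had a median difference of 0.37, and 31 glycolysis genes of -0.39, with 6 at least 2-fold lower. The normexp and quantile setting left 189 genes at least 2-fold apart.

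Interferon-stimulated genes were lower after IFNβ 1 h with TCR 6 h than after IFNβ 7 h. Mx1 had a scaled signal of 73400 after IFNβ 7 h and 616 after IFNβ 1 h with TCR 6 h, and Ifit1 stood at 100000 and 3570, Isg15 at 257000 and 73300 and Iigp1 at 64200 and 11700. The interaction term at 6 h is a different comparison, since it took IFNβ without TCR as the mean of the IFNβ 2 h and 7 h arrays. Its SEs rest on the difference between those 2 arrays and not on replicates. The interaction estimate at 6 h was -6.18 ± 1.60 for Iigp1, -5.23 ± 0.49 for Gbp5, -4.78 ± 1.19 for Mx1, -4.55 ± 0.55 for Usp18, -3.82 ± 0.50 for Ifit1 and -2.77 ± 0.68 for Isg15, but -0.28 ± 1.21 for Irf7. Outside these families, Gadd45g stood at -4.47, Cd274 at -4.46 and Tnfsf10 at -4.23. The median was -3.29 for 15 GTPases, 14 of which were lower adjusted over the list alone, and -1.80 for 57 antiviral genes, 3 of which were. It was -1.35 for B cell markers and -1.35 for NK cell markers, of which 3 were lower and 1 higher adjusted over the list alone, and the B cell list lay at -2.15 in IFNβ 1 h with TCR 6 h minus IFNβ 7 h. No gene passed over all 19866 in limma, 1639 had an unadjusted p under 0.05, and adjusted p was 0.50 for Gbp5. Median scaling moved the median of all genes in this term from -0.106 to 0.147.

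IFNβ effects late and early after its addition were compared in a further model (7 h alone or with TCR 6 h, against 2 h alone or with TCR 1 h). Estimates were 2.87 ± 0.88 for Cd86, 2.30 ± 0.51 for Ly6c1, 1.79 ± 0.45 for Ifi27l2a, 1.14 ± 0.47 for Irf7 and -1.57 ± 1.01 for Ifit1. The antiviral median was 0.12 and the GTPase median -0.79. The antiviral value averages opposite differences: the median went from 3.19 to 4.97 with IFNβ alone, and from 4.66 at 1 h to 2.32 at 6 h as the IFNβ difference with TCR. Limma called 0 of 19915 genes, with 764 at an unadjusted p under 0.05. Late and early arrays lay on different slides, and slide as a block left 1 call.

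Markers of other spleen cells were measured because the cells were purified magnetically and checked by flow cytometry for CD8α, B220 and CD11c. B cell markers had a median of -2.21 in the 6 h TCR response, and 13 of 16 fell, with Fcrla down by 4.15, Fcmr by 3.73 and Cd79b by 3.35 on the log2 scale. Cd79b had a scaled signal of 8570 and 8130 in untreated cells, 20800 after IFNβ 2 h, 18800 after IFNβ 7 h, 6920 after TCR 1 h and 1450 after TCR 6 h. On the IFNβ 2 h and 7 h arrays the B cell medians lay 1.57 and 1.19 above untreated, and in the IFNβ response the list stood at 0.50 with 0 of 16 called by limma. NK cell markers lay 1.62 and 1.75 above untreated on these arrays, with 11 of 12 genes higher on each, and class II genes 1.20 and 0.42 above, with 9 of 9 higher on each. Of 9 class II genes 8 fell at 6 h, with a median of -1.63, and of 12 natural killer (NK) cell markers 7 fell. Among 24 myeloid markers 8 fell and Hmox1 rose 7.95-fold. With slide as a block 3 class II genes, 4 NK cell markers and 3 myeloid markers were lower, and the class II median was -1.24. Of 9 CD4 T cell markers 3 rose at 6 h, Icos, Ccr4 and Izumo1r, and 0 of 9 erythroid markers were called by limma, with a median of -0.33.

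**Figure D4:**
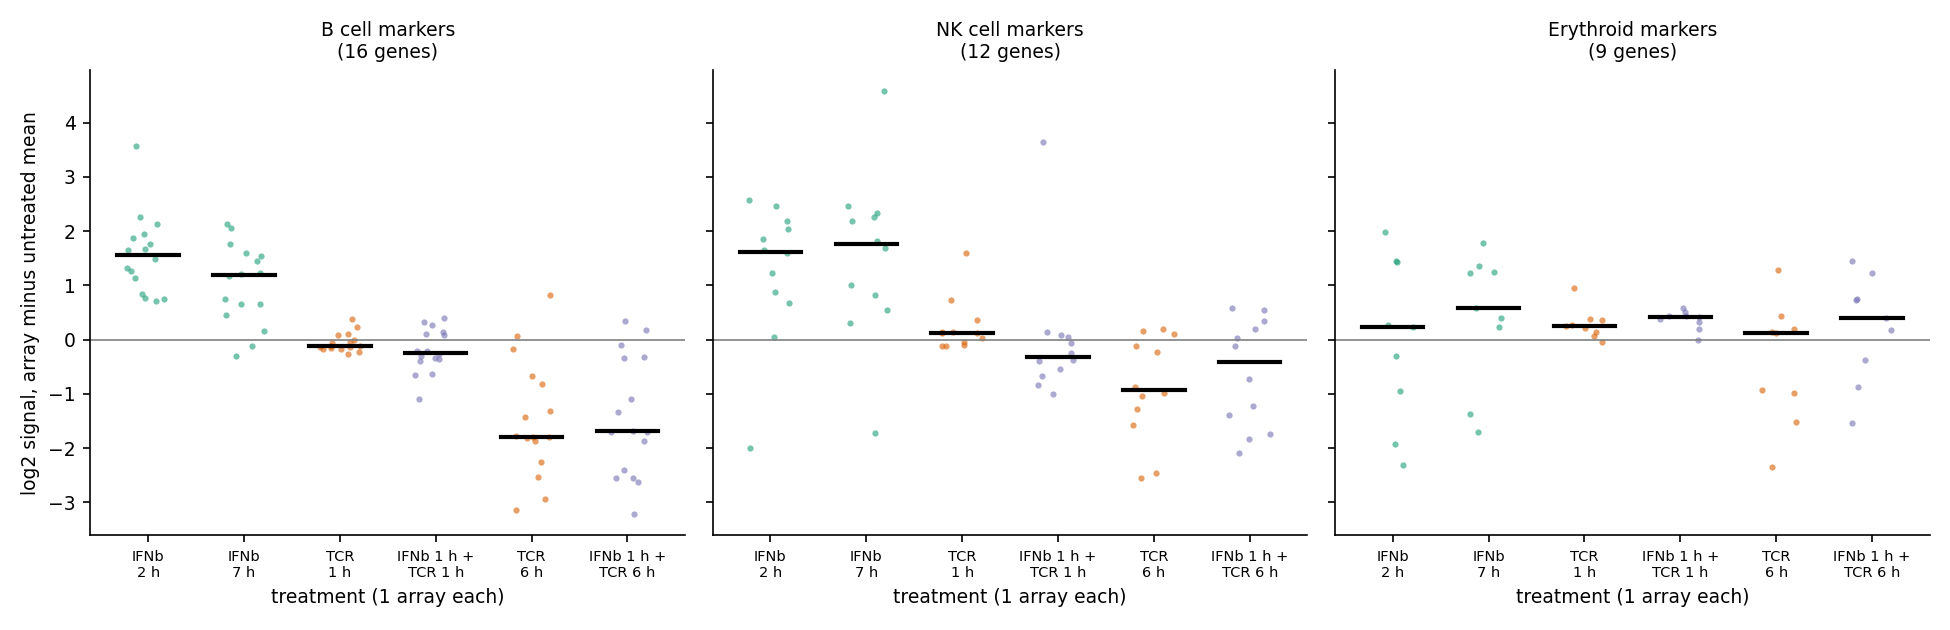
Log2 signal on each treated array minus the untreated mean for markers of B cells (16), NK cells (12) and erythroid cells (9); points are genes and black bars are medians. B cell medians were 1.57 and 1.19 after IFNβ 2 h and 7 h and -1.79 after TCR 6 h.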

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

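The comparisons and gene lists, the comparison of sample splits and the slide test of the interferon-stimulated genes were planned, and the other tests in this part were chosen only after the result was seen. Results were listed here where a test of a difference between 2 conditions passed, for lists with at least 3 members past the threshold adjusted over the list alone. For the IFNβ by TCR interaction at 1 h these were 8 cytokines and chemokines and 6 NK cell markers, all lower. For the interaction at 6 h they were 3 antiviral genes, 14 interferon-inducible GTPases and 4 NK cell markers. Between 6 h and 1 h of TCR stimulation 6324 genes passed. Of 34 splits of the samples that could be fitted, 2 gave at least the 10 calls of the IFNβ response: that split itself and 1 other with 268, which set untreated, TCR 1 h, TCR 6 h and IFNβ 1 h with TCR 6 h against the rest and called 17 of 57 antiviral genes and 14 interferon-inducible GTPases. Of its 268 genes 235 were higher on the side of IFNβ 2 h, IFNβ 7 h and IFNβ 1 h with TCR 1 h. Under the value table's naming, this structure of the samples follows IFNβ on 3 of its 4 arrays. The name of the array for IFNβ 1 h with TCR 1 h was chosen by antiviral genes. For such genes that array is no evidence that the structure follows IFNβ. The remaining splits gave 0 calls. By the number of splits alone, chance cannot be excluded for the count of 10.

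Interferon-stimulated genes were lower after IFNβ 1 h with TCR 6 h than after IFNβ 7 h. Scaling of the arrays is excluded as the sole cause of the low antiviral median in the interaction, which was -1.55 or lower over 3 scalings. The interaction averages the IFNβ 2 h and 7 h arrays. The difference between IFNβ 1 h with TCR 6 h and IFNβ 7 h was not itself taken under these scalings. Both arrays lay on slide 2, so by design a slide difference could not enter this pair. The antiviral median in the interaction taken within slide 2 was -2.43. Loss of interferon-responding B cells is not excluded. Between these 2 arrays the antiviral median lay 1.52 further down than that of the B cell list (difference -1.52). In the interaction the medians of the 2 lists lay closer together, so the values do not decide. TCR stimulation may lower these genes, but duration of IFNβ treatment cannot be told apart from it: 0 arrays had IFNβ for 1 h, a chase and no TCR stimulation. Whether IFNβ stayed on the cells during TCR stimulation is not given by the labels, so a difference in duration is itself uncertain.

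B cell markers were lower after TCR 6 h. The slide is excluded, since the median against untreated cells of the same slide was -1.68. A smaller share of B cells and lower expression within them cannot be told apart, and other causes were not tested. The log2 differences of 13 markers well above background had an SD of 0.999 and ranged from -3.14 to 0.07. The cells had been purified magnetically and checked by flow cytometry. A share measured on the same cells would bear on the first of these causes only.

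The scanner files and the value table give 2 arrays each other's identity. If the scanner files name them rightly, the array given IFNβ 1 h with TCR 1 h has an antiviral median of -0.14 against untreated, and the array without IFNβ has 4.44, so that naming is excluded if IFNβ was active. The value table's naming puts 4.44 on the array with IFNβ, which is in line with the arrays given IFNβ alone. The layout goes with the scanner files: under their naming both slides hold the conditions in the same order, and the value table's naming exchanges positions 3 and 4 on slide 1.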

How the results depend on the processing

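Alternatives for the untreated pair, the 2 disputed arrays, single slides and slide-relative values were tests chosen only after the data were seen. The cause was not tested for any value below. In the additive model, counts with slide as a block carry the length of IFNβ treatment as well as slide. The count for IFNβ (10) was 0 with normexp and quantile, 0 with quantile alone, 47 with median scaling, 18 with the series table, 74 with all 8 arrays above background, 36 with slide as a block, 79 with a variance trend, 41 with the level model, 84 with untreated arrays separate, 0 with the scanner files' assignment, 0 without the disputed arrays, 279 on slide 1, 0 on slide 2, and 0 to 275 with 1 array left out. The count for TCR 1 h (826) was 1886 with normexp and quantile, 532 with no filter, 1661 with all 8 arrays above background, 43 with slide as a block, 1789 with a trend, 280 with the level model, 2534 with untreated arrays separate, 356 with the scanner assignment, 429 on slide 1 and 30 to 810 with 1 array left out. For TCR 6 h (8921) slide as a block gave 5682 and leave-outs 4695 to 8888. For 6 h against 1 h (6324) they gave 0 and 2780 to 6323. The interaction at 1 h (0) was 2 with a trend and 65 with the scanner assignment, that at 6 h (0) was 5 with a trend, and late against early (0) was 1 with slide as a block. Lists called by camera, 13, 14 and 14 for IFNβ, TCR 1 h and TCR 6 h, were 0, 0 and 0 with an estimated correlation, and 7 for IFNβ with the scanner assignment. Genes at least 2-fold apart on single arrays numbered, with normexp and quantile and then with all 8 arrays above background, 1217 and 1761 (IFNβ 2 h), 1453 and 2141 (IFNβ 7 h), 1700 and 2392 (TCR 1 h), 1250 and 1771 (IFNβ with TCR 1 h minus TCR 1 h), and 189 and 426 (IFNβ with TCR 6 h minus TCR 6 h), and 5067 with normexp for TCR 6 h. No named gene that passed in the main fit changed sign, while Il2 in the interaction at 1 h, which had not passed, went from -3.72 to 4.46 with the scanner assignment. No paired analysis was possible because the labels give no pairing of cells between arrays. Not run for lack of arrays or residual degrees of freedom: cell means of the 7 conditions, TCR 1 h and 6 h against 1 h without the disputed arrays, single slides where a condition was absent, and the interactions with slide as a block, with a level model or without most treated arrays, and late against early on single slides or with the level model. Signal near background limits low genes such as Csf2 and Il3.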
